A study of Arabidopsis thaliana with 8 samples.

How the data were processed

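Chromatin of Arabidopsis thaliana seedlings 14 days old was analysed in 8 libraries: Myc ChIP and input from WT plants named after a 35S-SUC2 transgene and from a line with a Myc-tagged genomic MBD7 construct, 2 of each. Per the labels' protocols, plants grew at 23 °C with 16 h of light, 3 g of seedlings were fixed in 1% formaldehyde, chromatin was sonicated to about 500 bp and libraries were sequenced on an Illumina instrument. The labels name a Myc antibody from Invitrogen for WT ChIP and one from Millipore for MBD7 ChIP, while the protocol text names only the former. Groups and replicate numbers were taken from the sample titles.

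The deposited table held raw counts per window, whole numbers in windows of 1000 bp every 500 bp, and no normalized values were used. Per the submitters' processing notes, Bowtie2, SAMtools and featureCounts were used with TAIR10. Their versions, the treatment of reads with several alignments and any removal of duplicates are not given in the sources used here, so repeats can share reads between copies and counts are not known to be independent molecules. The table held 238296 windows on chromosomes 1 to 5, with 0 columns of other samples. Chloroplast and mitochondrial windows were not used here.

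Window coordinates are those of TAIR10. Gene names, biotypes and overlaps came from a RefSeq table of assembly TAIR10.1, from which no coordinates are printed, and all 90 genes of the lists were matched. A window was classed by the genes it overlapped, in the order protein-coding, pseudogene (which includes transposable element genes), RNA gene, or else intergenic. Gene counts were sums over the windows that overlap a gene, so neighbouring genes share counts, and 37898 of 37899 genes were tested. The pericentromere was set before the data were examined at 11 to 18 Mb of chromosome 1, 1 to 7 Mb of chromosome 2, 10 to 17 Mb of chromosome 3, 1 to 7 Mb of chromosome 4 and 9 to 16 Mb of chromosome 5. Windows with over 10 times the median input count, 1953 in all, were called copy-rich after the data were seen.

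The 5 comparisons (MBD7 ChIP against MBD7 input, MBD7 ChIP against WT ChIP, the interaction of genotype and precipitation, WT ChIP against WT input, and MBD7 input against WT input) were contrasts of 1 fit of all 8 libraries with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, the quasi-likelihood test, two-sided, and Benjamini-Hochberg adjustment at 0.05. The filter kept 232963 windows. Each window has 1 estimate of spread for all groups, though replicates agreed least in WT ChIP (r = 0.624), which also has the fewest counts. If WT ChIP varies more than the inputs beyond its low counts, that estimate is too small for it and too large for the inputs. Scaled counts (cpm) use TMM factors. TMM takes most windows as unchanged, so fold changes are relative to them, and the TMM factors of ChIP and input libraries lay far apart, from 0.447 to 2.08. Class and list tests used camera with a preset correlation of 0.01 and with an estimated one, and fry (limma 3.58.1). The data.table package was version 1.17.8, and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

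The named windows are, for each comparison with a ChIP library, the 10 with the highest and 5 with the lowest log2 fold change (5 and 5 between the inputs) among those that passed, had a mean of at least 10 counts per library and had both replicates of 1 group above both of the other, with touching windows taken once. Of touching windows the one with the smaller p was named, so its log2 fold change can be below that of its neighbour or of windows that were not named. Every member of 9 lists was examined: methylation machinery, demethylation machinery, methyl-CpG-binding family, methylated reporter loci, demethylation target genes, Polycomb targets, photosynthesis genes, reference genes and the transgene loci. The rule and lists were written with the pericentromere bounds. Folds against 0 counts are bounds from 3 counts per library, and ratios with 1 to 3 counts have 95% counting intervals, both covering counting error only.

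The tests were run on simulated data in which each library was drawn from the mean of the inputs at its own scaled size, with 100 windows or genes changed by 2-fold and 100 by 4-fold. Of 225585 simulated windows tested, the 2-fold and 4-fold changes recovered were 27 and 79 for MBD7 ChIP against input, 3 and 33 for MBD7 ChIP against WT ChIP, 0 and 28 for the interaction, 3 and 42 for WT ChIP against input and 72 and 94 for the inputs, with 5, 2, 4, 1 and 10 false calls. Of 37897 genes they were 91 and 100, 56 and 90, 49 and 89, 61 and 95, and 94 and 100, with 28, 19, 23, 10 and 10 false calls. Lower changes were recovered less often than higher ones in windows. Far fewer windows and genes were changed here than were called in the comparisons with a ChIP library. The adjusted p depends on that number. Simulated ChIP libraries also took the profile of the inputs over windows, and all groups had the same trend of spread. These rates and false calls thus need not hold for the data.

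Alternatives were DESeq2's size factors, scaling by library size only, DESeq2's Wald test (DESeq2 1.42.0), no filter and a filter of 20 counts in 2 libraries, a fit of only the groups compared, the replicate number as a block over all groups or within genotype, a test against a 1.5-fold change, and each library left out. Chosen after seeing the data were every second window, which removes overlaps, fits without copy-rich windows, and MBD7 ChIP thinned to the depth of WT ChIP (21.5% of counts kept). After a first test of shared reads in WT ChIP was known, 12 other sets of windows were looked at. The first test had for a time been replaced by 1 of them and its prediction rewritten, and both were put back. No reference genome was used here, so a planned relation to CG density was not analysed.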

Results

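Binding of MBD7, an Arabidopsis protein of the methyl-CpG-binding domain family, was mapped by chromatin immunoprecipitation and sequencing in seedlings 14 days old. WT plants, whose sample names give a SUC2 transgene driven by the 35S promoter, were set beside a line that expresses a genomic MBD7 construct with 4 Myc tags from the MBD7 promoter. Each genotype gave 2 libraries precipitated with an antibody to Myc (ChIP) and 2 libraries of chromatin before precipitation (input), so the 8 libraries formed 4 groups of 2. The WT plants carried no tagged protein, and their ChIP libraries measured the background of the precipitation.

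Counts were analysed in windows of 1000 bp that start every 500 bp along chromosomes 1 to 5 of TAIR10. The WT input libraries held 31459707 and 24679699 counts. The MBD7 input libraries held 26739116 and 19224696. The MBD7 ChIP libraries held 25846940 and 23761267 counts, whereas the WT ChIP libraries held 7450486 and 4971029. WT ChIP had medians of 4 and 3 counts per window against 12 and 13 in MBD7 ChIP. The 100 windows with the most counts over all 8 libraries held 55.6% to 61.4% of the counts of each ChIP library, against 22.7% to 31.8% for the inputs. Log counts of the replicates correlated across windows, which are not independent, with r = 0.968 in WT input, 0.960 in MBD7 input, 0.914 in MBD7 ChIP and 0.624 in WT ChIP. No label says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

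The input libraries of the genotypes were compared first, since extra copies of MBD7 mark the transgenic line. Scaled counts (cpm) over the MBD7 gene (AT5G59800) were 95.6 ± 0.218 in MBD7 input and 12.4 ± 0.496 in WT input (SD, n = 2). Its log2 difference was 2.94 ± 0.15 (SE; adjusted p = 3.26e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The raised stretch spanned 9 windows on chromosome 5, from 24094001 to 24099000, over MBD7 and part of its neighbour SBT5.4. Log2 differences were 3.65 in the window from 24096001 and 2.85 in that from 24097501 over SBT5.4. SUC2 (AT1G22710), a sucrose transporter gene, had 36.5 ± 1.79 cpm in MBD7 input and 35.7 ± 5.89 in WT input, a log2 difference of 0.03 ± 0.15 that did not pass the test. Both inputs stood above the neighbouring windows there: the window from 8032001 had 5.59 cpm in WT input and 5.57 in MBD7 input, against at most 1.77 in each for windows of this locus outside SUC2. The inputs thus showed no difference between the genotypes in copies of SUC2. Whether both carry extra copies was not tested apart from this depth.

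Outside this stretch the number of windows called between the inputs depended on the fit. With all 8 libraries in the fit, a window on chromosome 5 from 2071501 was higher in MBD7 input by 1.70 ± 0.24 on the log2 scale, and AT3G03855, a transcribed pseudogene on chromosome 3, by 1.67 ± 0.33. The last window of chromosome 4, from 18585001 to 18585056, had a log2 difference of -2.38 ± 0.36. In the pericentromere of chromosome 3 the RNA genes AT3G06365 (-1.3 ± 0.22) and AT3G00660 (-1.28 ± 0.22) and the window from 14192001 (-1.19 ± 0.21) were lower in MBD7 input, as was the window of chromosome 1 from 15436001 (-1.08 ± 0.18). In this fit 25 windows of 232963 were higher and 21 lower at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the 10 named windows only the 3 over MBD7 and SBT5.4 passed without each of the 8 libraries in turn. Without MBD7 input replicate 1 the count was 18 windows and without MBD7 ChIP replicate 2 it was 547. The other 7 windows no longer passed without 1 or more of the input libraries. Their log2 differences over all left-out libraries were 1.63 to 1.74 (5: 2071501), 1.46 to 1.88 (AT3G03855) and -2.65 to -2.11 (4: 18585001). Those of the lower windows in the pericentromere were -1.40 to -1.23 (AT3G06365), -1.36 to -1.22 (AT3G00660), -1.39 to -0.995 (3: 14192001) and -1.24 to -0.92 (1: 15436001). Scaling by library size alone moved the median over all windows from 0.00 to 0.21 and called 1192 windows higher and 120 lower. DESeq2's size factors gave 20 higher and 42 lower, 32.3% of the calls being higher against 54.3%. A fit of the input libraries alone called 663 windows higher and 1552 lower, and DESeq2's Wald test 73 higher and 227 lower.

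The inputs also differed by class. Windows in the arms had a median log2 difference of 0.04, and the pericentromere, which holds all other windows, one of -0.105. With the preset correlation both passed camera (adjusted p = 1.97e-09 each). With an estimated correlation the arms passed camera (adjusted p = 5.42e-05) and the pericentromere did not (adjusted p = 0.133). Both tests weigh the same contrast and part only by the estimated correlation, 0.000257 in the arms and 0.0532 in the pericentromere. Windows with over 10 times the median input held 42.8% and 39.0% of the counts in WT input and 33.0% and 34.8% in MBD7 input.

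MBD7 ChIP was compared with MBD7 input to find where the tagged protein was enriched. The pericentromeres carried most of the enrichment: 35098 of their 63342 windows were higher in MBD7 ChIP, with a median log2 fold change of 0.98. In the arms 6998 of 169621 windows were higher. In the gene table used, pseudogenes include transposable element genes, and their windows in the pericentromere had the strongest median among the gene and intergenic classes, 1.54. Of these, 19886 of 22932 were higher. Pseudogene windows in the arms had a median of 0.50, with 1927 of 4281 higher. This class pools 2 biotypes that differed by gene in the arms. Transcribed pseudogenes had a median of -0.151, with 47 of 477 higher and 51 lower, and other pseudogenes one of 0.695, with 339 of 559 higher. Windows of protein-coding genes in the arms had a median of -0.30, with 3221 of 138297 higher and 13116 lower. Intergenic windows of the pericentromere had a median of 1.23, and the 12 windows over annotated rRNA genes had one of 3.28.

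**Figure D1:**
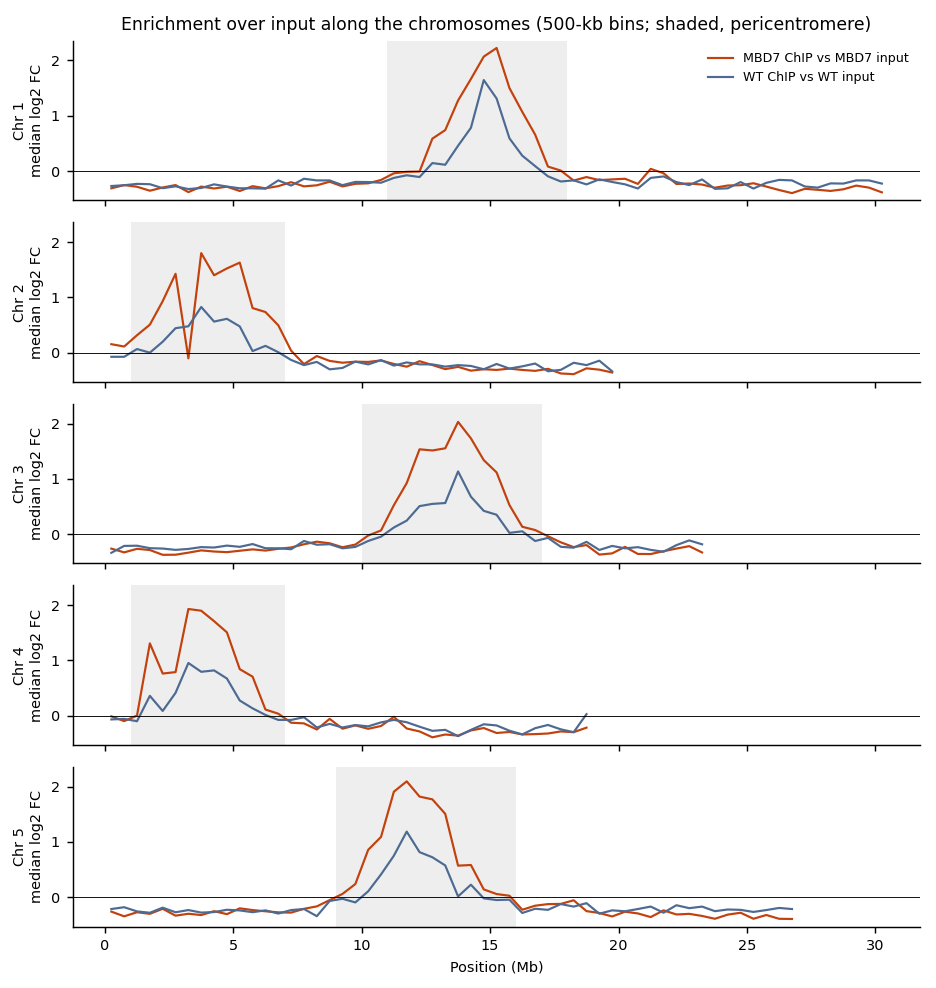
Median log2 fold change per window in bins of 500 kb (y axis) along the 5 chromosomes (x axis, Mb), for MBD7 ChIP against MBD7 input and WT ChIP against WT input, with the pericentromeres shaded. Both lines rise over most of the pericentromeres, where the medians over all windows were 0.98 and 0.33. In the bin of chromosome 2 from 3 Mb, MBD7 ChIP against input falls to -0.10.

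Across all 232963 windows, 42096 were higher and 14426 lower in MBD7 ChIP than in its input at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 74.5% of the calls being higher. The higher windows merged into 4196 regions of 23.5 Mb in all. In a competitive set test (camera) with an estimated correlation, the adjusted p was 7.05e-03 for the pericentromere. It was 1.04e-02 and 3.81e-02 for pseudogene windows in the pericentromere and the arms and 3.26e-06 for the lower values of protein-coding windows in the arms. These directions are relative to all windows: with library size as the only scaling the median of all windows moved from -0.10 to -2.15. Then 3772 windows were higher and 213930 lower, 1.73% of the calls being higher.

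**Figure D2:**
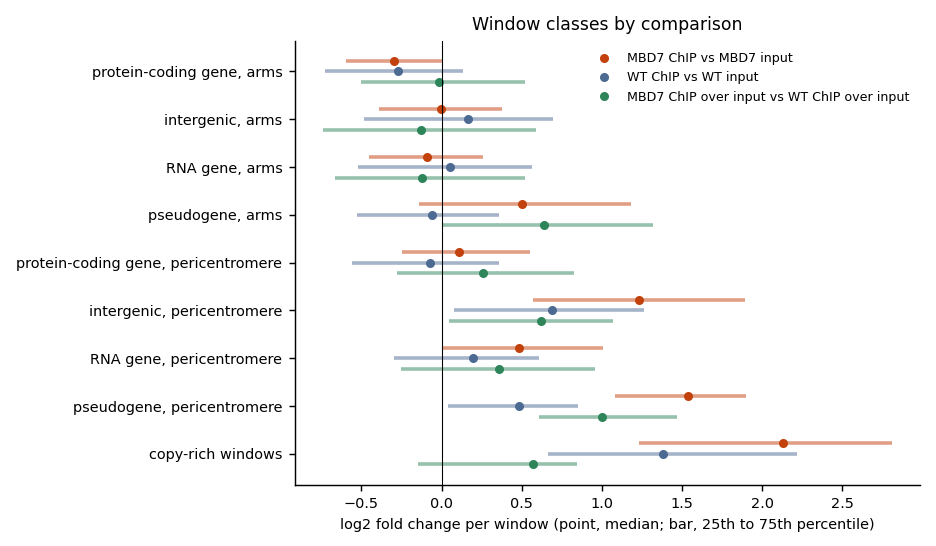
Log2 fold change per window (x axis; points are medians and bars the 25th to 75th percentiles) by window class (y axis) for MBD7 ChIP against input, WT ChIP against input and the difference between these. Pseudogene windows in the arms lie at 0.50 in MBD7 ChIP and -0.06 in WT ChIP.

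The windows with the largest changes included single sites and repeats. A window over the long non-coding RNA gene AT4G06975 (chromosome 4, 11208501 to 11209500) rose by 5.06 ± 0.22 on the log2 scale, from 1.64 ± 0.105 cpm in MBD7 input to 55.0 ± 18.8 in MBD7 ChIP (SD, n = 2). In the pericentromere of chromosome 3, windows over AT3G00660 (start 14193501, 4.96 ± 0.26), AT3G06365 (14204001, 4.92 ± 0.26), the microRNA gene MIR5642a (14196501, 4.33 ± 0.23) and intergenic DNA (14192001, 4.23 ± 0.23, and 14254501, 4.41 ± 0.23) rose. At the end of chromosome 2, AT2G01022 (10001, 4.46 ± 0.23) and AT2G01008 (2501, 4.33 ± 0.23) rose. Of these 7 windows all but that from 14254501 were windows with over 10 times the median input, where copies of a repeat may share reads. The pseudogene AT1G34590 (chromosome 1, 12666001, 4.19 ± 0.20) and the protein-coding gene AT4G19270 (chromosome 4, 10537501, 4.05 ± 0.22) also rose and, like AT4G06975, were not among those windows. AT4G19270 was at 3.45 without MBD7 ChIP replicate 2. With library size as the only scaling these 10 rises were 2.02 to 2.96 and still passed. WT ChIP, without tagged protein, was also above WT input in those with over 10 times the median input. AT3G00660 had 6356 cpm in WT ChIP, 621 in WT input and 7979 in MBD7 ChIP, and AT3G06365 had 4249, 437 and 5353. MBD7 input was at 255.8 and 177.4 cpm there, so these rises cannot be put down to tagged protein alone. At 14254501, AT1G34590, AT4G19270 and AT4G06975 WT ChIP had 0.6507, 0.7107, 1.49 and 8.323 cpm, against 40.59, 21.57, 27.07 and 55.0 in MBD7 ChIP. The lower windows chosen by the same rule had 1 count in MBD7 ChIP: AtCDC48C had a ratio to input of 0.0671 (95% counting interval 0.00170 to 0.374), and AT2G41810 and AT5G65575 each one of 0.0763 (0.00193 to 0.425). The window of chromosome 2 from 16789501 had one of 0.0811 (0.00205 to 0.452) and AT1G55220 one of 0.0905 (0.00229 to 0.504). These intervals cover counting error only, and none of these 5 windows passed with MBD7 ChIP thinned to the depth of WT ChIP or with DESeq2's Wald test. With their MBD7 ChIP counts of 0 and 1, AT5G65575 and AT1G55220 no longer passed without MBD7 ChIP replicate 1, which left a count of 1. The window from 16789501, with counts of 1 and 0, did not pass without replicate 2.

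Among the genes of 9 lists written before the data were examined, SUC2, where both inputs stood above the neighbouring windows, rose most. It rose by 1.48 ± 0.15 on the log2 scale, from 36.5 ± 1.79 to 101 ± 2.53 cpm, and MBD7 by 1.1 ± 0.14, from 95.6 ± 0.218 to 205 ± 2.48 (SD, n = 2). MBD7 also rose in WT ChIP, which has no tagged protein, by 1.38 ± 0.19. Of 12 genes of the DNA methylation machinery 3 rose and 3 fell (3 and 4 when adjusted over the list alone). NRPD1, the largest subunit of RNA polymerase IV, rose by 0.90 ± 0.13, with NRPE1 (0.68 ± 0.19) and DCL3 (0.54 ± 0.14). DDM1 (-0.49 ± 0.14), CMT3 (-0.47 ± 0.15) and MET1 (-0.45 ± 0.15) fell. Of 13 loci used as reporters of DNA methylation 3 rose and 1 fell (4 and 2 when adjusted over the list alone). The values were 0.91 ± 0.22 for QQS, 0.74 ± 0.20 for AGL36, 0.73 ± 0.14 for the transposon gene AtMu1 and -0.49 ± 0.13 for PAI2. Of 13 targets of Polycomb silencing SEP3 (-0.80 ± 0.19), ABI3 (-0.68 ± 0.16) and AP1 (-0.56 ± 0.17) fell and KNAT1 (0.72 ± 0.21) rose (1 rose and 5 fell when adjusted over the list alone). Of 10 genes of the methyl-CpG-binding family MBD7 and MBD2 (0.37 ± 0.13) rose and MBD11 (-0.74 ± 0.17), MBD8 (-0.64 ± 0.21), MBD4 (-0.61 ± 0.22) and MBD10 (-0.58 ± 0.17) fell (4 and 4 when adjusted over the list alone).

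**Figure D3:**
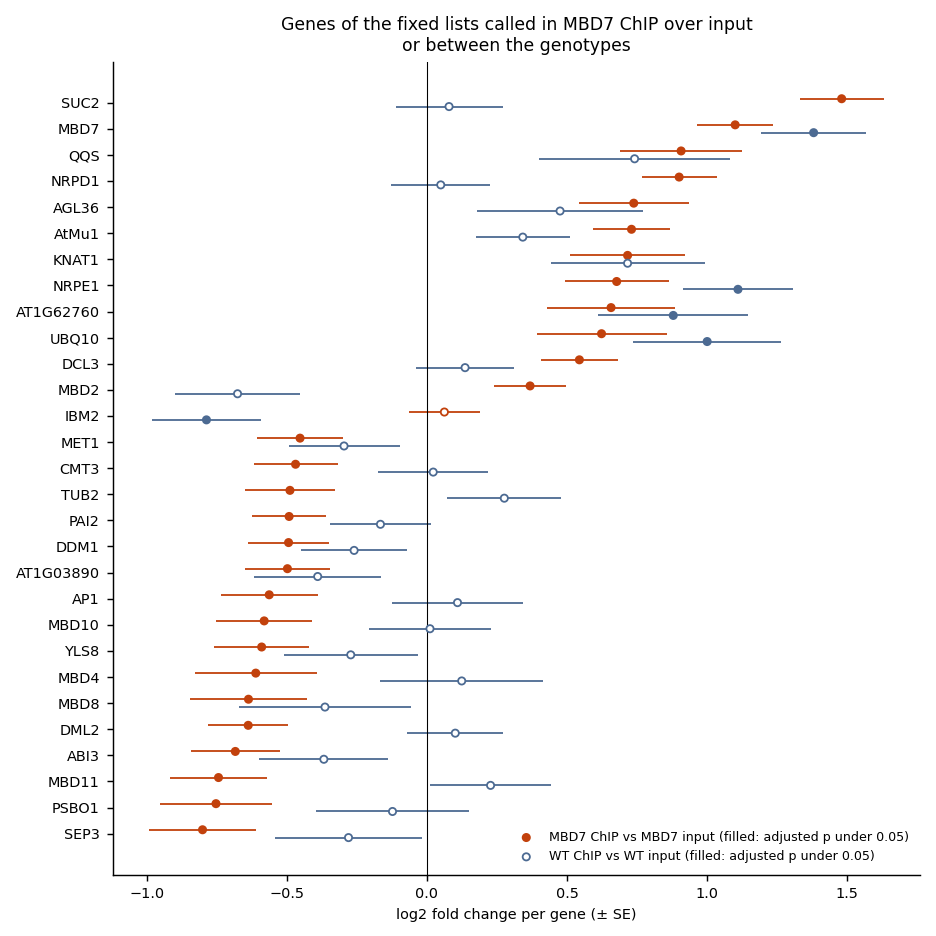
Log2 fold change per gene with its SE (x axis) for genes of the lists (y axis) in MBD7 ChIP against input and WT ChIP against input, filled where the adjusted p was under 0.05. SUC2 lies at 1.48 in MBD7 ChIP and 0.08 in WT ChIP, while MBD7 lies at 1.1 and 1.38.

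In the other lists DML2 (-0.64 ± 0.14) fell among 9 genes of active DNA demethylation (1 when adjusted over the list alone). AT1G62760 (0.66 ± 0.23) rose and AT1G03890 (-0.50 ± 0.15) fell among 7 target genes of demethylation (1 and 1). UBQ10 (0.62 ± 0.23) rose and YLS8 (-0.59 ± 0.17) and TUB2 (-0.49 ± 0.16) fell among 11 reference genes (0 and 2). PSBO1 (-0.75 ± 0.20) fell among 15 photosynthesis genes (1). No list passed camera: the lowest adjusted p was 0.0553 for the transgene loci, 0.594 with an estimated correlation. By fry, which tests only direction within the set and does not compare with other genes, the adjusted p was 7.1e-03 for methylation reporters (up), 7.1e-03 for Polycomb targets (down) and 6.7e-03 for the transgene loci (up). The calls for SUC2, MBD7, NRPD1, AtMu1 and QQS passed without each of the 8 libraries in turn, though not with library size alone. Without MBD7 ChIP replicate 1 SEP3 no longer passed, nor MBD11 without MBD7 ChIP replicate 2 and KNAT1 without MBD7 input replicate 2. Their lowest and highest values over the left-out libraries were -0.88 and -0.58, -0.77 and -0.55, and 0.55 and 0.93. Each other list gene named here as changed in MBD7 ChIP against input no longer passed without 1 or more libraries of MBD7 input, MBD7 ChIP or both. Of these UBQ10 ranged from 0.09 to 1.13, NRPE1 from 0.34 to 1.08 and MET1 from -0.60 to -0.16.

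The directions of the list genes were relative to all genes and depended on the scaling. The falls of DDM1, CMT3, MET1, MBD4, MBD8, MBD10, AP1, TUB2 and AT1G03890 no longer passed with DESeq2's size factors or its Wald test. With the Wald test PAI2, YLS8, UBQ10 and AT1G62760 did not pass either. With library size as the only scaling SUC2 had a value of 0.0511 that did not pass. In that fit MBD7 (-0.325), NRPD1 (-0.521), NRPE1 (-0.725), DCL3 (-0.883), MBD2 (-1.05), QQS (-0.521), AGL36 (-0.683), AtMu1 (-0.697), KNAT1 (-0.706), AT1G62760 (-0.762) and UBQ10 (-0.774) were lower in MBD7 ChIP. Over all genes 6383 were higher and 5087 lower, 55.6% of the calls being higher. DESeq2's size factors gave 7018 and 2397 (74.5%), its Wald test 6680 and 1730 (79.4%) and library size alone 1835 and 33409 (5.21%). Of the list genes SUC2, MBD7 and NRPD1 alone passed a threshold of 1.5-fold.

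MBD7 ChIP was compared with WT ChIP to set the signal against the background of the precipitation. The pericentromere was higher in MBD7 ChIP, with a median log2 fold change of 0.53 and 10785 windows higher. Pseudogene windows had medians of 0.81 in the pericentromere, 7923 being higher, and 0.60 in the arms, 1084 being higher. Protein-coding windows in the arms had one of 0.02. Over MBD7 the difference was 2.67 ± 0.17 and over SUC2 1.43 ± 0.19. This comparison does not take out the extra copies of MBD7 in the MBD7 line. NRPD1 (0.91 ± 0.18), MBD2 (1.16 ± 0.22), IBM2 (0.86 ± 0.20) and MBD9 (0.55 ± 0.17) were higher in MBD7 ChIP. MBD11 (-0.98 ± 0.25), DML2 (-0.79 ± 0.19) and TUB2 (-0.71 ± 0.23) were lower.

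In many of the windows with the largest difference, both WT ChIP libraries were at 0, so the fold is a lower bound from a floor of 3 counts per library. AT1G69550 (chromosome 1, 26149501) was at least 8.54-fold higher in MBD7 ChIP, the intergenic window of chromosome 3 from 6992001 at least 4.04-fold and AT3G13370 (4341501) at least 3.30-fold. AT1G09905 (chromosome 1, 28788501) was at least 3.19-fold higher, AT5G61910 (24861001) at least 3.15-fold and ty2 (chromosome 1, 16397001) at least 3.10-fold. AT2G20010 (8637501) was at least 2.31-fold higher, AT2G12340 (4970001) at least 2.27-fold and AGO10 (chromosome 5, 17614001), an Argonaute gene, at least 2.26-fold. AT1G20400 (chromosome 1, 7075001), with 5 and 6 counts in WT ChIP, was higher by 3.13 ± 0.33 on the log2 scale. Lower windows were AT2G40050 (chromosome 2, 16723501, -3.96 ± 0.34), VPS60.2 (chromosome 5, 1409001, -3.13 ± 0.25), and intergenic windows of chromosome 4 from 2296501 (-3.59 ± 0.43) and chromosome 1 from 20826501 (-2.82 ± 0.40) and 13894001 (-2.57 ± 0.30). The window from 2296501 had 17 and 77 counts in the WT ChIP libraries, and its value was -1.96 without WT ChIP replicate 2 and -4.47 without replicate 1. That from 20826501 was at -4.94 with MBD7 ChIP thinned to the depth of WT ChIP. Without MBD7 ChIP replicate 1 the bounds of AT1G09905 and AT2G12340 fell to 1.91-fold and 1.46-fold.

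In all, 13466 windows were higher and 1143 lower at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 92.2% of the calls being higher. Of the higher windows, 248 had 0 counts in WT ChIP. With an estimated correlation the adjusted camera p was 2.71e-02 for each of the pericentromere and the pseudogene windows of arms and pericentromere. It was 4.14e-04 for protein-coding windows in the arms. Their median of 0.02 lay below the 0.16 of all windows, while 1281 of them were called higher and 686 lower. Among the lists the transgene loci passed camera (adjusted p = 3.16e-10) but not with an estimated correlation (adjusted p = 0.0737). Fry gave an adjusted p of 0.0027 for the transgene loci and 0.0466 for each of the methyl-CpG-binding family (up), the photosynthesis genes (down) and the Polycomb targets (down). The median of the family was -0.19 and its mean 0.17, of other sign. Both this family and the transgene loci hold MBD7, whose extra copies enter this comparison. Over the other settings the inputs differed at MBD7 by 2.9 to 3.05 on the log2 scale. Neither list was tested without MBD7. When adjusted over the list alone 3 genes of the methyl-CpG-binding family were higher and 2 lower, and both transgene loci, 1 methylation reporter and 1 methylation machinery gene were higher. In the demethylation machinery 1 gene was lower, and the other lists had 0. The photosynthesis genes and Polycomb targets also had 0 over all genes.

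Without WT ChIP replicate 2, 8512 windows differed. The calls for MBD11 and DML2 did not pass without WT ChIP replicate 1 or MBD7 ChIP replicate 2 (ranges over the left-out libraries -1.04 to -0.70 and -0.89 to -0.53). That for MBD9 passed in 3 of 8 (0.50 to 0.76) and that for TUB2 in 0 of 8 (-0.74 to -0.47). MBD9 (0.316) did not pass with library size alone, nor TUB2 with DESeq2's size factors or its Wald test. Over all genes 3384 were higher and 1137 lower (74.9% higher), and with library size alone 2156 and 2773 (43.7%). A fit of only these groups called 1872 genes higher and 245 lower, of 37077 tested. Scaling by library size alone moved the median of all windows from 0.16 to -0.045 and gave 8319 windows higher and 1922 lower, 81.2% of the calls being higher. The labels name another vendor's Myc antibody for each genotype, so genotype and antibody cannot be told apart in this comparison.

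The enrichment over input was then compared between the genotypes by an interaction term, which takes out differences between the inputs. SUC2 was more enriched in the MBD7 line by 1.40 ± 0.24 on the log2 scale (adjusted p = 6.18e-04, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and MBD7 itself had a value of -0.28 ± 0.23 that did not pass. MBD2 (1.04 ± 0.26), NRPD1 (0.85 ± 0.22) and IBM2 (0.85 ± 0.23) were more enriched in the MBD7 line, and MBD11 (-0.97 ± 0.28) and DML2 (-0.74 ± 0.22) less. With library size alone MBD2 (0.712), NRPD1 (0.511) and IBM2 (0.515) did not pass, nor DML2 with DESeq2's size factors or its Wald test. SUC2 passed in each of 17 other settings. Over all genes 3358 were more and 886 less enriched (79.1% higher), and with library size alone 1891 and 2836 (40%). Pseudogene windows had medians of 1.00 in the pericentromere, with 8963 of 22932 higher, and 0.64 in the arms, with 1023 of 4281 higher. The pericentromere as a whole had one of 0.67 with 12689 higher, and protein-coding windows in the arms one of -0.02. Setting windows without WT ChIP counts at their bound left medians of 1.00, 0.63, 0.66 and -0.03 for these classes. By gene in the arms, transcribed pseudogenes had a median of -0.0908 and other pseudogenes one of 0.587.

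AT1G69550 was at least 15.8-fold more enriched in the MBD7 line, the window of chromosome 3 from 6992001 at least 14.0-fold, and AT1G09905 at least 6.46-fold. In the same test ty2 was at least 3.47-fold more enriched, AT3G13370 at least 3.41-fold, AT2G10540 (4090501) at least 2.77-fold, AT2G12340 at least 2.74-fold and AT1G49938 (chromosome 1, 18486001) at least 2.60-fold. These bounds take the inputs as measured, and the window from 6992001 and AT1G09905 had few and uneven counts in MBD7 input, 19 and 2 and 14 and 3. Without MBD7 input replicate 1 their bounds were 53-fold and 13.7-fold. Without MBD7 input replicate 2 the bound of 6992001 was 8.07-fold, and without MBD7 ChIP replicate 1 those of AT1G09905 and AT2G12340 were 3.88-fold and 1.76-fold. That of AT1G49938 was 1.63-fold without MBD7 ChIP replicate 2. WT ChIP was itself at least 7.27-fold below WT input over AT1G69550 and at least 2.5-fold over AT1G49938. These falls enter the bounds, and for AT1G49938 the fall comes near to its whole bound of 2.60-fold. AT1G20400 (7075501) had a log2 difference of 3.72 ± 0.45 and the window of chromosome 2 from 4244001 one of 1.99 ± 0.31. Less enriched in the MBD7 line were AT2G40050 (-4.36 ± 0.38, and -4.99 without WT input replicate 1) and AT3G03855 (-5.01 ± 0.82), the latter with 14 and 1 counts in WT ChIP. With 1 or 2 counts in MBD7 ChIP, AT1G78260 had a ratio of 0.0555 (95% counting interval 0.00672 to 0.200), AT5G43310 one of 0.0587 (0.00711 to 0.212) and the window of chromosome 3 from 5046001 one of 0.0491 (0.00124 to 0.273). Without WT ChIP replicate 1 AT3G03855, AT1G49938, AT1G78260, AT5G43310 and the window from 5046001 no longer passed. AT3G03855 then had a count of 1 in WT ChIP and a log2 value of -2.30. The window from 5046001 failed without 6 of the 8 libraries, and AT5G43310 also without MBD7 ChIP replicate 1.

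In all, 15237 windows were more and 1336 less enriched in the MBD7 line at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 91.9% of the calls being higher. The adjusted camera p with an estimated correlation was 2.03e-02 for the pericentromere and for its pseudogene windows and 2.59e-02 for pseudogene windows in the arms. It was 2.79e-04 for protein-coding windows in the arms. Their median of -0.02 lay below the 0.15 of all windows, while 1248 of them were called higher and 730 lower. No list passed camera or fry: the lowest adjusted p were 0.316 and 0.0795. Adjusted over the list alone 2 genes of the methyl-CpG-binding family, 1 methylation reporter, 1 methylation machinery gene and 1 transgene locus were higher. In the same adjustment 1 gene each of the methyl-CpG-binding family and demethylation machinery was lower, and the other lists had 0. The count fell to 9691 and 10222 without WT input replicate 1 or 2, 9028 and 10497 without MBD7 input replicate 1 or 2, and 10205 without WT ChIP replicate 2. Of the list genes SUC2 alone passed without each library in turn (1.21 to 1.74). The calls failed without 2 of 8 libraries for MBD2 (0.99 to 1.3) and 4 for NRPD1 (0.67 to 1.19). They failed without 5 for IBM2 (0.76 to 1.16), 6 for MBD11 (-1.04 to -0.70) and 7 for DML2 (-0.85 to -0.50). Scaling by library size alone moved the median of all windows from 0.15 to -0.26 and gave 5748 windows higher and 2761 lower, 67.6% of the calls being higher.

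WT ChIP was compared with WT input as a measure of the background without tagged protein. All 12 windows over rRNA genes were higher, with a median of 2.37. Of windows with over 10 times the median input 1477 of 1953 were higher and 0 lower, with a median of 1.38, against 2.13 in MBD7 ChIP. The pericentromere had a median of 0.33, its pseudogene windows one of 0.48 and its intergenic windows one of 0.69, and pseudogene windows in the arms one of -0.06. MBD7 rose by 1.38 ± 0.19 on the log2 scale, from 12.4 ± 0.496 to 32.7 ± 7.41 cpm (SD, n = 2), and NRPE1 (1.11 ± 0.20), UBQ10 (1.00 ± 0.27) and AT1G62760 (0.88 ± 0.27) also rose. IBM2 (-0.79 ± 0.20) and DME (-0.55 ± 0.17) fell, and SUC2 had a value of 0.08 ± 0.19 that did not pass.

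**Figure D4:**
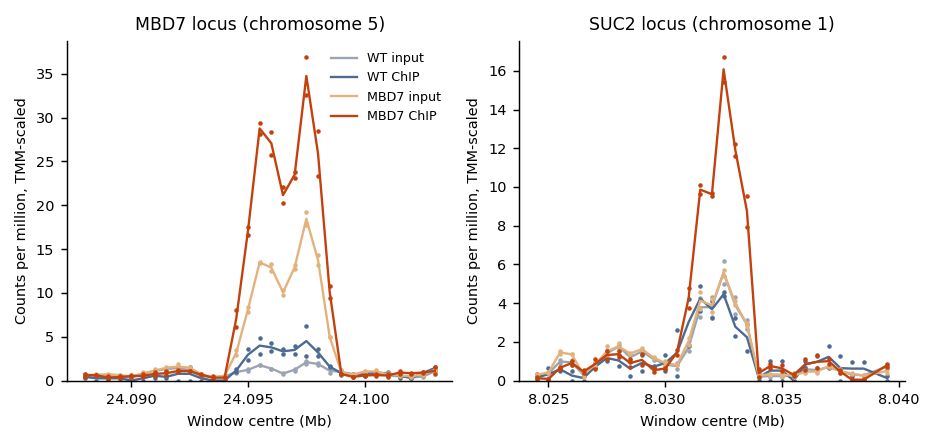
Scaled counts (cpm, y axis; lines are means and dots the 2 libraries of each group) in windows along the MBD7 and SUC2 loci (x axis, Mb). Over MBD7 the input of the MBD7 line lies above that of WT and WT ChIP above WT input, while over SUC2 only MBD7 ChIP stands above the other 3 groups.

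Most of the highest windows in WT ChIP were intergenic: on chromosome 2 those from 3092501 (4.03 ± 0.29), 3634001 (3.84 ± 0.41), 5099001 (3.70 ± 0.27), 3698001 (3.69 ± 0.34), 3629001 (3.48 ± 0.20) and 3612001 (3.05 ± 0.23). Others were on chromosome 1 that from 19027001 (4.11 ± 0.34), on chromosome 4 that from 2985501 (3.74 ± 0.50) and on chromosome 5 that from 15207001 (3.63 ± 0.46), beside VPS60.2 (1409501, 3.96 ± 0.24). The WT ChIP libraries had uneven counts of 84 and 23 in the window from 3092501, 178 and 43 in that from 5099001 and 12 and 57 in that from 3634001. Without WT ChIP replicate 1 the values of the first 2 were 2.98 and 2.55, and that of 3634001 was 4.72. Without WT ChIP replicate 2 the window from 3634001 was at 2.14 and that from 19027001 at 3.47. Without WT input replicate 1 the latter and VPS60.2 were at 4.8 and 4.66. With library size alone the 10 rises were 1.4 to 2.48 and still passed. AT1G69550 was at least 7.27-fold lower in WT ChIP than in input, AT1G49938 at least 2.5-fold and AT2G35040 (14765001) at least 2.26-fold. MAPKKK7 (chromosome 3, 4413001) was at least 2.06-fold and AT1G76920 (28892001) at least 1.91-fold lower. Without WT ChIP replicate 1 the window from 15207001 (then 2.49), AT1G49938 and AT1G76920 no longer passed.

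In all, 11960 windows were higher and 1063 lower in WT ChIP at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 91.8% of the calls being higher. The adjusted camera p with an estimated correlation was 7.64e-03 for windows with over 10 times the median input, 3.53e-02 for the pericentromere and 0.0544 for the pericentromere without those windows. It was 0.127 for its pseudogene windows, 0.985 for those of the arms and 1.68e-04 for the lower protein-coding windows in the arms. No list passed camera (lowest adjusted p 0.171) or fry (0.133). Adjusted over the list alone 1 gene rose in each of the demethylation targets, methyl-CpG-binding family, methylation machinery and transgene loci, and 1 rose and 1 fell among reference genes. In that adjustment 1 fell in the methyl-CpG-binding family, the demethylation machinery and the methylation reporters, and the photosynthesis genes and Polycomb targets had 0. Without WT ChIP replicate 1 the count fell to 6245 windows. Without 1 or more of the WT libraries UBQ10 (0.66 to 1.32), AT1G62760 (0.35 to 1.23), IBM2 (-1.01 to -0.61) and DME (-0.79 to -0.36) no longer passed, whereas MBD7 (1.16 to 1.61) and NRPE1 (0.98 to 1.26) passed in all 8. With library size alone MBD7 (0.293), NRPE1 (0.0368), UBQ10 (-0.0718) and AT1G62760 (-0.218) did not pass and SUC2 (-1) was lower. DME did not pass with DESeq2's size factors, nor AT1G62760 with its Wald test. Over all genes 2889 were higher and 617 lower (82.4% higher), and with library size alone 256 and 30256 (0.839%). Scaling by library size alone moved the median of all windows from -0.09 to -1.74, with 1638 windows higher and 193907 lower, 0.838% of the calls being higher.

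Between the inputs, camera with an estimated correlation passed for the transgene loci (adjusted p = 6.43e-03) and the methyl-CpG-binding family (adjusted p = 0.0131), both of which hold MBD7, the 1 list gene called over all genes and when adjusted over the list alone. Fry gave adjusted p of 4.49e-03 and 0.0112 for these lists. With all 8 libraries in the fit 2 of all genes were higher and 2 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1698 had an unadjusted p under 0.05. A fit of the input libraries alone called 317 genes higher and 811 lower, and DESeq2's Wald test 154 higher and 100 lower.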

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

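All tests below were chosen only after the results they weigh were seen. For depth and for single-copy input the limits were written before the value of the test was known.

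These results are listed because the enrichment over input differed between the genotypes by the interaction test (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05). It called 15237 windows more and 1336 less enriched in the MBD7 line. Relative to all windows, class medians were 0.52 for the pericentromere, 0.85 for its pseudogene windows, 0.49 for pseudogene windows in the arms and -0.17 for protein-coding windows in the arms. Gene values were 1.40 for SUC2, 1.04 for MBD2, 0.85 for NRPD1, 0.85 for IBM2, -0.97 for MBD11 and -0.74 for DML2 on the log2 scale. With library size alone MBD2, NRPD1 and IBM2 did not pass, nor DML2 with DESeq2's size factors. Windows with WT ChIP at 0 were at least 15.8-fold (AT1G69550), 14.0-fold (chromosome 3, 6992001), 6.46-fold (AT1G09905), 3.47-fold (ty2), 3.41-fold (AT3G13370), 2.77-fold (AT2G10540), 2.74-fold (AT2G12340) and 2.60-fold (AT1G49938) more enriched. These bounds take the inputs as measured, and with 1 library left out they fell to 8.07-fold for 6992001, 3.88-fold for AT1G09905, 1.76-fold for AT2G12340 and 1.63-fold for AT1G49938. Without MBD7 input replicate 1 those of 6992001 and AT1G09905 rose to 53-fold and 13.7-fold. Falls of WT ChIP below WT input enter the bounds of AT1G69550 (at least 7.27-fold) and AT1G49938 (at least 2.5-fold). For AT1G49938 the fall comes near to the whole bound. AT1G20400 (3.72), the window of chromosome 2 from 4244001 (1.99), AT3G03855 (-5.01, and -2.30 without WT ChIP replicate 1) and AT2G40050 (-4.36, and -4.99 without WT input replicate 1) differed on the log2 scale, and AT1G78260, AT5G43310 and the window of chromosome 3 from 5046001 had ratios of 0.0555, 0.0587 and 0.0491.

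WT ChIP, from plants without tagged MBD7, was raised over the MBD7 transgene. Its median against WT input was 1.15 over the 9 windows, 4 of them called higher, and -0.65 in 20 flanking windows. This rise was examined for shared reads. Reads of MBD7 ChIP in the WT ChIP libraries may account for it, at a share of 9.52% (95% counting interval 6.77% to 12.7%): over 200 other windows strongly enriched in MBD7 ChIP, WT ChIP held 7.28 times the count needed (6.40 to 8.14), but 174 of these lie in the pericentromere, where WT ChIP has signal of its own, so that the ratio decides little. All 12 sets of enriched windows that were then tried, after that ratio was known, are counted here, and they overlap. With the WT input background added, the count reached that needed by the lower share in 9 of the 12. Every set in the pericentromere reached it, which decides little for the same reason. In the arms the answer was mixed: 3 of the 6 sets fell short (0.453 to 0.885 of it) and the others reached 1.28 to 1.36 of it. The arm set with the highest minimum, a log2 value of 3, and single-copy input had 82 counts. That was below both the 181.2 needed and the 107.8 of the background alone. Reads of MBD7 input or of the construct would need a share of 20.5% of MBD7 input (14.6% to 27.4%). They cannot be told apart from reads of MBD7 ChIP, as no other window marks them. No biological explanation was tested.

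Windows with over 10 times the median input were raised in WT ChIP (median 1.38, 95% interval 0.89 to 1.93 from resampled blocks of 100 kb). Reads from MBD7 ChIP at the upper share above predict a median of 0.44, below that interval, so they do not suffice. Better recovery of repeated DNA in a precipitation without a bound protein remains possible: such windows took 76.2% or more of the counts of each WT ChIP library and 42.8% or less of each WT input. Unspecific binding would give the same, and no sample separates them. No biological explanation was tested.

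Pseudogene windows in the arms were more enriched in the MBD7 line (0.49 relative to all windows). By gene this held for pseudogenes not marked as transcribed (median 0.587, 215 of 559 higher). Transcribed pseudogenes in the arms had a median of -0.0908, with 18 of 477 higher. The tests below pool both biotypes, whose mix at single-copy depth was not examined. Thinning MBD7 ChIP to the depth of WT ChIP gave 0.52, above the limit of 0.3 set before the test. Thinning leaves the expected ratio in each window unchanged, and 21 of the 4281 windows were at 0 in WT ChIP. The median could thus hardly fall, so this test says little about the difference in depth. Reads shared between repeat copies may account for part: in the 2039 of 4281 windows at single-copy input depth the median was 0.26 (95% interval 0.16 to 0.34), between the limits of 0.1 and 0.3 set before the test. The antibody, of another vendor in each genotype, cannot be told apart from the genotype, and WT ChIP over input alone gave 0.0309. Binding of the tagged MBD7, the difference the design names, stays open beside these and was not tested apart from them.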

How the results depend on the processing

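Every second window, fits without copy-rich windows and thinning of MBD7 ChIP were chosen after seeing the data; all other settings were planned. Depth limits the comparisons with WT ChIP, which had medians of 4 and 3 counts per window. In simulated windows the interaction recovered 0 of 100 changes of 2-fold and 28 of 100 of 4-fold. Far fewer windows were changed in the simulation than were called in the data. The adjusted p depends on that number, so these recoveries need not hold for the data. Where leaving out a library leaves a group with 1 library, that library is assumed to vary like the others. Windows on organelle genomes (not used here) and CG density (no genome used here) were not run. Over all settings 57 results of named windows and 275 of list genes were calls lost; 0 windows and 73 gene values reversed, all of the latter with library size alone.

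Counts of windows are in the order MBD7 ChIP against input, MBD7 ChIP against WT ChIP, interaction, WT ChIP against input, inputs. Library size alone gave 217702, 10241, 8509, 195545 and 1312, and by construction moved all windows; pseudogene windows in the arms of WT ChIP then passed camera at 0.0252 relative to all windows. The 1.5-fold threshold gave 34230, 5680, 6551, 6210 and 10, and every second window 28251, 7322, 8280, 6574 and 23, from fewer windows tested. Thinning gave 29800, 6279 and 7792 for the first 3 and 300 for the inputs, the first 3 with fewer counts. Only the groups compared gave 6268 for MBD7 against WT ChIP, from 102883 windows tested, and 2215 for the inputs. These fits do not share an estimate of the spread with the other groups. Genes called in MBD7 against WT ChIP also fell, from 4521 to 2117, with 37077 of 37898 tested. Fewer features tested thus do not alone account for the fall. The cause of neither change was tested further. DESeq2's Wald test gave 300 for the inputs, with 34966 tested; the cause was not tested. It called 92.8% of its windows higher in MBD7 ChIP against input, and fits without copy-rich windows 61.4%. Those fits moved the median of all windows from -0.10 to -0.21, 0.16 to 0.04 and 0.15 to 0.04 in the first 3 comparisons, and 40% of the calls between the inputs were higher. Left-out libraries gave 41376 to 63102, 8512 to 17235, 9028 to 20257, 6245 to 14024 and 18 to 547. The class medians of the pericentromere and of pseudogene windows in the arms in comparisons with a ChIP library kept their side of the threshold in every setting but that named. Copy-rich windows in MBD7 against WT ChIP reversed relative to all windows, from 0.06 to -0.0363 (only the groups compared), -0.0839 (without WT ChIP replicate 2) and -0.0367 (without MBD7 ChIP replicate 1), the highest left-out value being 0.155; the cause was not tested.

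The replicate numbers are not stated to pair the samples, and deviations between groups showed no sign of it (correlations from -0.00583 to 0.0345). With few counts per ChIP window this check cannot exclude a pairing. With the replicate block the counts were 55733, 14604, 16366, 12917 and 57, and within genotype 51856, 13287 and 11980 for MBD7 ChIP against input, the interaction and WT ChIP against input. The block ended the calls of MET1, MBD2 and MBD4 in MBD7 ChIP against input, TUB2 in MBD7 against WT ChIP and DME in WT ChIP against input. Within genotype those of MET1, CMT3, DDM1, MBD2, MBD4, MBD8, PAI2, AT1G03890, TUB2, YLS8 and AP1 ended in MBD7 ChIP against input, DML2, MBD11, IBM2 and the window from 5046001 in the interaction, and DME in WT ChIP against input.

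Gene counts that moved by over 1.5 times, against 11470, 4521, 4244, 3506 and 4, were as follows. Library size alone gave 35244, 30512 and 31 for MBD7 ChIP against input, WT ChIP against input and the inputs. The 1.5-fold threshold gave 4569, 1198, 1384, 976 and 2. Only the groups compared gave 2117 for MBD7 against WT ChIP and 1128 for the inputs. Thinning gave 6299 for MBD7 ChIP against input and 18 for the inputs, and DESeq2's Wald test 254 for the inputs. Left-out libraries gave as the lowest 6664, 2240 and 1752 for MBD7 ChIP against input, the interaction and WT ChIP against input, and 2 to 89 for the inputs. With MBD7 ChIP thinned, AT2G12340, AT1G49938, AT1G78260, AT5G43310, IBM2, MBD11 and DML2 no longer passed in the interaction, nor AT2G12340, DML2, MBD11, IBM2 and TUB2 in MBD7 ChIP against WT ChIP. In MBD7 ChIP against input, of the list genes SUC2, MBD7, NRPD1, NRPE1, DCL3, DML2, AtMu1, SEP3, AT1G03890 and UBQ10 alone still passed. With only the groups compared, MET1, CMT3, MBD4, AT1G03890, TUB2 and AP1 no longer passed in MBD7 ChIP against input, DML2, MBD9, MBD11, IBM2 and TUB2 in MBD7 against WT ChIP and DME in WT ChIP against input. The 1.5-fold threshold left of the list genes MBD7 and SUC2 in MBD7 against WT ChIP, SUC2 in the interaction and MBD7 in WT ChIP against input.

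Library size alone turned the sign of 73 gene values by construction, since it moved the median of all genes to -1.57 in MBD7 ChIP against input and to -1.11 in WT ChIP against input. In MBD7 ChIP against input the called rises turned for NRPD1 (-0.521), NRPE1 (-0.725), DCL3 (-0.883), MBD2 (-1.05), MBD7 (-0.325), QQS (-0.521), AGL36 (-0.683), AtMu1 (-0.697), AT1G62760 (-0.762), UBQ10 (-0.774) and KNAT1 (-0.706). Of genes not called before, these were then lower: ROS1 (-1.11), IDM2 (-1.21), IDM3 (-1.2), APE1L (-1.39), KYP (-1.31), RDR2 (-1.32), MBD5 (-0.871), MBD9 (-1.13), FWA (-1.05), SDC (-1.14), IBM2 (-1.36), FIS2 (-1.03), EPF2 (-0.705), AT1G26380 (-1.04), AT1G26390 (-1.24), AT1G26400 (-1.15), ACT2 (-1.4), ACT7 (-1.2), TIP41 (-1.39), UBC21 (-1.35), RBCS1A (-1.18), RBCS1B (-1.31), RBCS3B (-1.32), LHCB2.1 (-1.2), LHCB2.2 (-1.2), PSAD1 (-1.1), PSAF (-1.39) and AG (-1.23). In WT ChIP against input the called rises turned for AT1G62760 (-0.218) and UBQ10 (-0.0718), neither passing. Of genes not called before, these were then lower: DML2 (-0.985), DML3 (-0.88), CMT3 (-1.06), NRPD1 (-1.03), DCL3 (-0.947), MBD1 (-0.816), MBD4 (-0.964), MBD6 (-0.982), MBD10 (-1.07), MBD11 (-0.864), PHE1 (-0.705), MEA (-0.728), FIS2 (-1.08), AtMu1 (-0.747), AT1G26390 (-0.721), AT1G26400 (-0.942), AT1G26410 (-0.993), TUB2 (-0.812), RBCS1A (-0.845), RBCS1B (-0.777), LHCB1.1 (-0.884), LHCB1.2 (-0.852), LHCB1.3 (-0.893), LHCB2.1 (-0.985), RCA (-0.696), CA1 (-1.04), FLC (-1.05), AG (-0.757), STM (-1.07), AP1 (-0.98), SHP1 (-1) and SUC2 (-1).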

Other observations

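The groups described here were chosen after their values were seen. A cluster of 81 tRNA genes on chromosome 1 (AT1G56730 to AT1G57530, windows 21268001 to 21309000) was enriched in both genotypes, in the arm and away from the pericentromere. All 81 genes were higher in MBD7 ChIP than in its input (median log2 fold change 1.31, range 1.04 to 1.61) and all 81 in WT ChIP (median 1.49, range 0.89 to 2.1). In the interaction test 0 of the 81 differed (median -0.12), and 1 was lower in MBD7 ChIP than in WT ChIP. Neighbouring genes of this cluster share windows, so the 81 values are not independent and describe 1 region.

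Of the 5 LpxC genes, which encode a deacetylase of lipid A synthesis and lie on chromosome 1, LpxC2 alone was more enriched over input in the MBD7 line, by 2.15 on the log2 scale (adjusted p = 5e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and it was higher in MBD7 ChIP than in input by 2.68. The other 4 had interaction values of 0.33 to 0.46 and did not pass. Against WT ChIP, MBD7 ChIP was higher over LpxC2 (2.1), LpxC3 (0.59), LpxC4 (0.56) and LpxC5 (0.57), and LpxC1 (0.52) did not pass. Reads may be shared between related members of this group, which was not tested.

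Between 3 and 3.5 Mb of chromosome 2 the median over 973 windows was -0.10 in MBD7 ChIP against input and 0.48 in WT ChIP against input, and the interaction had a median of -0.53. The inputs differed there too: MBD7 input against WT input had a median of 0.389 in this bin and -0.147 and -0.247 in the bins on either side. MBD7 ChIP against WT ChIP had one of -0.122 in this bin and 0.797 and 0.645 beside it. Most of the interaction median itself thus came with the inputs. The contrast with the neighbouring bins came with both the ChIP libraries and the inputs. The bins on either side had medians of 1.43 and 1.80 in MBD7 ChIP and 0.44 and 0.83 in WT ChIP. The AT1G69550 window from 26150001 also differed between the inputs, by -0.93, and overlaps that at 0 counts in WT ChIP, which was not called between the inputs.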
